A study of Mus musculus with 28 samples.

How the data were processed

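The series lists 28 libraries, 16 of gene expression and 12 of cell hashing, in 3 batches. Per the file headers, the authors counted UMIs with Cell Ranger 6.1.1 in batches 1 and 2 and 7.1.0 in batch 3. The deposited matrices hold whole-number counts per gene and cell barcode, together with counts of 5 hashtags per batch, and list barcodes with at least 500 UMIs. Per the submitters' processing notes the genome build was mm10 and Seurat was used. The deposited reference tables tie each hashtag to a mouse number. Barcodes of a batch share one suffix, so the libraries of a batch could not be separated and each batch was treated as one pool of 5 mice. Nothing states which mouse had which treatment, and comparisons of conditions planned before the data were examined could not be made.

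Hashtags were assigned per batch with HTODemux of Seurat 5.3.0 at a quantile of 0.99, which left 16281 singlets, 2748 doublets and 251 negatives of 19280 barcodes. Cells with at least 500 UMIs, at least 250 genes and under 15% mitochondrial UMIs were kept. Doublets within a mouse carry one hashtag and remain. Scrublet marked 2, 4 and 2 cells in the 3 batches, under 0.5%, and so did not work here, and no cell was removed by it. Clustering used 2000 variable genes, without the genes of the interferon, MHC and checkpoint lists and without mitochondrial genes, log values per 10000 UMIs centred and scaled within batch, 30 principal components, 15 neighbours and Leiden resolution 1 in scanpy 1.11.5. Clusters were called "like" a cell type from markers fixed before the data were examined, with at least 3 markers detected in at least 10% of the cells. The rule that turns marker levels into a name, the highest mean z-score of a type's markers over clusters, was set after the clusters were seen. Clusters under 20 cells, or of low depth without a leading marker of their own, stayed unnamed. So did clusters whose 10 leading genes held at least as many markers of another type, 1 or more, as of their own. Among the unnamed were cluster 8 with S100a8 and Ace, cluster 11 with Gm42418 and cluster 12 with Ccr3 and Alox15. Cluster 12 scored highest for eosinophils (3.486), with 1 eosinophil and 1 neutrophil marker among its leading genes.

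Counts were summed per mouse and class. For the Cd274 comparison, cells with at least 1 Cd274 UMI and cells with none were drawn in equal number per mouse within 10 bins of UMI depth, giving 3941 cells on each side with median depths of 5259 and 5241 UMIs, and Cd274 was left out of the test. Sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) with mouse as a block, because both sums come from the same mouse, and lists with camera at a correlation of 0.01 and with an estimated one in limma 3.58.1. Lists of the Cd274 comparison were also tested with limma's fry, and calls of lists are camera's unless fry is named. Standard errors were derived from the fold change and the F statistic. DESeq2 1.42.0 was an alternative. Adjusted p under 0.05 was the threshold. Named genes are the 12 with the highest and the 12 with the lowest fold change among genes past the threshold with at least 20 CPM and one direction in all 3 batches, together with genes of the fixed lists. Predicted, ribosomal protein and mitochondrial genes are counted and not named, and some results of single genes are not reported here. Batches were compared by the same test on all cells of a mouse. Levels were compared between classes and clusters, and the odds ratio against 0, by exact sign flips over mice, and relations across mice by 100000 permutations, with NK cell-like cells as the lymphoid share. Lists that share genes with the cell type markers were not tested between classes.

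On simulated counts with 50 genes changed by each fold, the Cd274 test recovered 40, 49, 50 and 50 genes at folds of 1.25, 1.5, 2 and 0.5, with 16 false calls among 7898 genes. The test of batches 3 and 1 recovered 6, 29, 47 and 44, with 5 false calls among 11137 genes. Totals per mouse ran from 3858718 to 8984121 UMIs. Intervals of shares are exact binomial intervals at 95% and cover counting error only. Alternatives covered the cell filter, hashtag rule, depth matching, clustering resolution, the names of clusters with nearly tied scores, normalization, count filter, mouse block, and leaving out each mouse or batch. Gene positions and intron lengths came from GENCODE M21.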

Results

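Single-cell RNA sequencing with hashtag antibodies was carried out on mouse cells sorted for the surface proteins CD11b, CD11c or both, in a study of mice bearing P815 mastocytoma tumours and of macrophages that carry PD-L1, the ligand of the checkpoint receptor PD-1. Cells of 5 mice were pooled in each of 3 batches, and the 15 mice served as replicates. No treatment, response or tissue is given for any mouse in the sources used here, so no comparison of conditions was made and the cells are described without naming their tissue. The 3 matrices held 6202, 8744 and 4334 barcodes with a median of 5394, 5411 and 6806 UMIs. After removal of hashtag doublets and shallow cells, 16105 cells were kept, between 517 and 1605 per mouse.

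Macrophage-like and monocyte-like cells together made up most of the sorted cells. Macrophage-like cells, led in different clusters by C1qa, Ccl8, Cxcl9, Mmp12 or the stress genes Hspa1b and Hmox1, formed 53.7% ± 8.04 of the cells of a mouse (SD, n = 15), and monocyte-like cells, led by Vcan and Chil3 or by Cxcl10 and Gbp5, formed 20.8% ± 3.93. Type 2 conventional dendritic cell-like cells formed 7.75% ± 2.48, natural killer (NK) cell-like cells with Gzma, Prf1 and Ncr1 formed 2.76% ± 2.12, and cDC1-like, migratory dendritic cell-like and plasmacytoid dendritic cell-like cells averaged 0.904% ± 0.399, 0.599% and 0.196%, with up to 1.78% cDC1-like cells in a mouse. Clusters without a name held 13.2% ± 6.07. Cluster 8, which held 4.93% ± 2.23, scored 1.253 for neutrophils and 0.988 for monocytes and is not in the monocyte-like share. At resolutions 0.5 and 2, clusters of 631 and 634 cells led by Pou2f2 and Ace were named monocyte-like. The border between macrophage-like and monocyte-like cells was not sharp: cluster 3, led by Ly6i, Cxcl9 and Cfb, had a macrophage score of 0.645 and a monocyte score of 0.636, with no macrophage marker among its leading genes. Cluster 6, led by Hspa1b, had scores of 0.535 and 0.497. Clusters 5, 6 and the monocyte-like cluster 7 also had no marker of their own class among their leading genes. The scores of cluster 5 lay farther apart, with 0.612 for macrophages and -0.044 for monocytes. Cluster 7 scored 0.953 for monocytes and 0.444 for neutrophils, its second type. With cluster 3 counted as monocyte-like the shares were 43.4% ± 7.14 macrophage-like and 31.1% ± 5.2 monocyte-like cells. With clusters 3 and 6 both moved they were 36.5% ± 6.96 and 38.1% ± 5.78, and at a clustering resolution of 2 they were 35.1% ± 7.56 and 36.7% ± 6.05, so that the order of both classes turned. At resolution 0.5 they were 62.6% ± 6.79 and 3.64% ± 1.71. The sort on CD11b and CD11c sets these shares, and lymphocytes that lack both proteins are not represented.

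**Figure D1:**
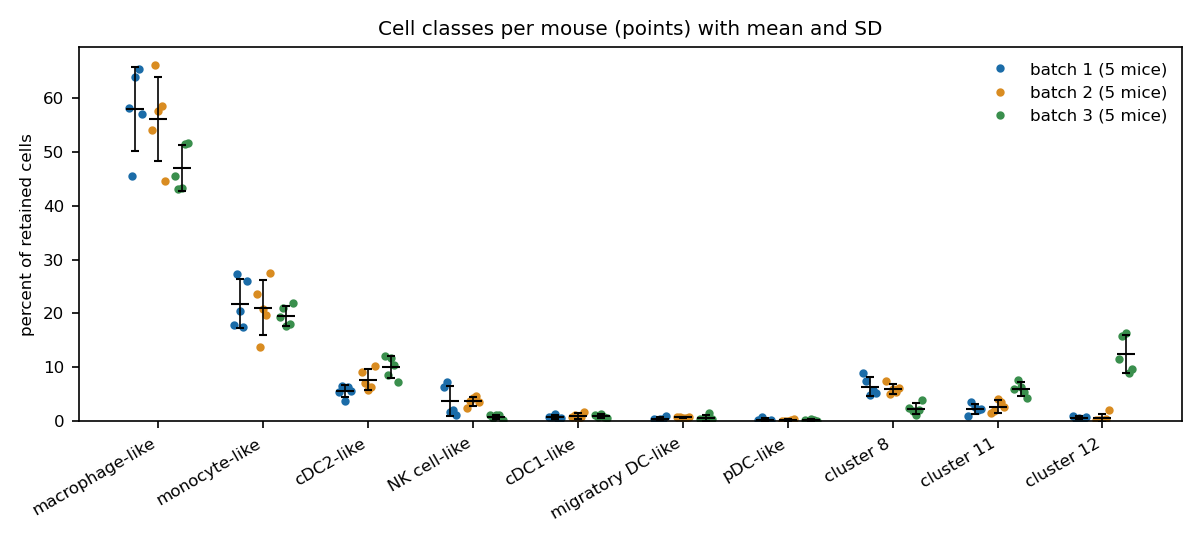
Percent of retained cells (y axis) in each named class or unnamed cluster (x axis) for each mouse (points, coloured by batch), with the mean and SD of the 5 mice of a batch as black bars. With the names as drawn, macrophage-like cells took the highest share in each batch and cluster 12 held 12.5% of the cells in batch 3, while with clusters 3 and 6 counted as monocyte-like the order over all mice turned (36.5% against 38.1%).

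The first comparison asked which genes accompany Cd274, the gene of PD-L1, within monocyte-like and macrophage-like cells, together called mononuclear phagocytes here. Cells with a Cd274 UMI had more transcripts of Slamf7, a receptor of the SLAM family, with 96.4 CPM against 30.5 in cells without one (log2 fold change 1.67 ± 0.07, SE). They also had more of Inhba, a subunit of activin (1.64 ± 0.10), of Nos2, the inducible nitric oxide synthase (1.54 ± 0.11), and of Acod1, which makes itaconate (1.36 ± 0.08), each higher in 15 of 15 mice. Cd163, a scavenger receptor of haemoglobin complexes, fell by 2.08 ± 0.31 on the log2 scale (higher in 1 of 15 mice), and Pf4, a chemokine, and Folr2, a folate receptor, fell by 1.26 ± 0.17 and 1.07 ± 0.11. Of 7978 genes tested, 1412 were higher and 1270 lower in the Cd274-positive cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with mouse as a block. Other genes named by the fixed rule were Cd200, Rsad2, Hcar2, Gpnmb, Tent5c, Ifit2 and Cmpk2, between 1.23 and 1.60 higher on the log2 scale, and Cbr2, Ltc4s, Psd3, Ednrb, Cd209a, Slc9a9, Tmem8, Ccl6 and Fcgrt, which were lower.

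Interferon-gamma response genes rose with Cd274. Of 28 measured genes of this list 27 were higher and 0 lower, the same counts when adjusted over the list alone, with a mean log2 fold change of 0.71. Examples are Cxcl10 (1.20 ± 0.12, adjusted p = 1.25e-08), Iigp1 (1.09 ± 0.09, adjusted p = 6.31e-11) and Cxcl9 (0.88 ± 0.14, adjusted p = 9.85e-06, higher in 13 of 15 mice) in edgeR's test. Ciita, the master regulator of MHC class II genes, was the member that did not pass (56.8 CPM against 57.6). Genes of the type I interferon response rose in 16 of 17 cases and in 17 when adjusted over the list alone, with a mean of 0.67. Both lists passed camera's test with adjusted p of 1.29e-35 and 8.22e-15, and with adjusted p of 0.000868 and 0.0098 with an estimated correlation.

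Genes of hypoxia and glycolysis also rose. All 15 measured members were higher, also when adjusted over the list alone, among them Vegfa, the vascular growth factor (0.92 ± 0.04), Egln3, an oxygen sensor (0.87 ± 0.08), and the glucose transporter gene Slc2a1 (0.57 ± 0.04). The list mean was 0.48, with camera's adjusted p = 6.34e-29, and adjusted p = 0.000474 with an estimated correlation. Lymphocyte chemoattractants, which share Cxcl9 and Cxcl10 with the interferon-gamma list, rose in 4 of 4 cases with a mean of 0.90. MHC class I genes rose in 15 of 18 (mean 0.23) and checkpoint and costimulatory genes in 7 of 11 (mean 0.26), including Pdcd1lg2, the gene of PD-L2 (0.68 ± 0.11), and these counts did not change when adjusted over the list alone. Inflammatory cytokine genes rose in 8 of 12 cases, led by Ccl4 and Ptgs2, and 1, Cxcl1, was lower, against 9 higher and 2 lower when adjusted over the list alone (mean 0.18). These 4 lists passed camera's test with adjusted p of 1.21e-05, 1.22e-08, 0.00212 and 0.00399, and with an estimated correlation at adjusted p of 0.0115, 0.0098, 0.0098 and 0.031.

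MHC class II genes did not rise with Cd274. Of 7 measured genes 0 were higher and 2, H2-DMb1 and H2-DMb2, were lower, with a list mean of -0.12 (camera's adjusted p = 0.182). H2-Ab1 stood at 1771 CPM in the positive and 1880 CPM in the negative cells. Monocyte chemoattractant genes fell in 4 of 6 cases, and in 5 when adjusted over the list alone, led by Ccl6 and Ccl9, with a list mean of -0.50 (camera's adjusted p = 4.51e-05, and adjusted p = 0.0098 with an estimated correlation). Genes of alternative activation went both ways, with 3 higher, Vegfa among them, and 3 lower, Cd163 and Folr2 among them, of 10. Their mean was -0.21 while their median was 0.02 and camera's direction was up (adjusted p = 0.338). Of 13 dissociation stress genes 5 were higher and 2 lower, or 6 and 2 when adjusted over the list alone (mean 0.07, adjusted p = 0.182), 1 cell cycle gene was tested without a call, and no cytotoxic gene was tested. Of 13 genes of lipid-associated macrophages 6 were higher, Gpnmb among them, and 2 lower (mean 0.21, camera's adjusted p = 0.0205), and this result was lost with an estimated correlation (adjusted p = 0.29). Fry, the other list test planned, called the dissociation stress, alternative activation and lipid-associated lists as higher (adjusted p of 0.0171, 0.0365 and 0.00364). MHC class II did not pass by fry (adjusted p = 0.172).

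**Figure D2:**
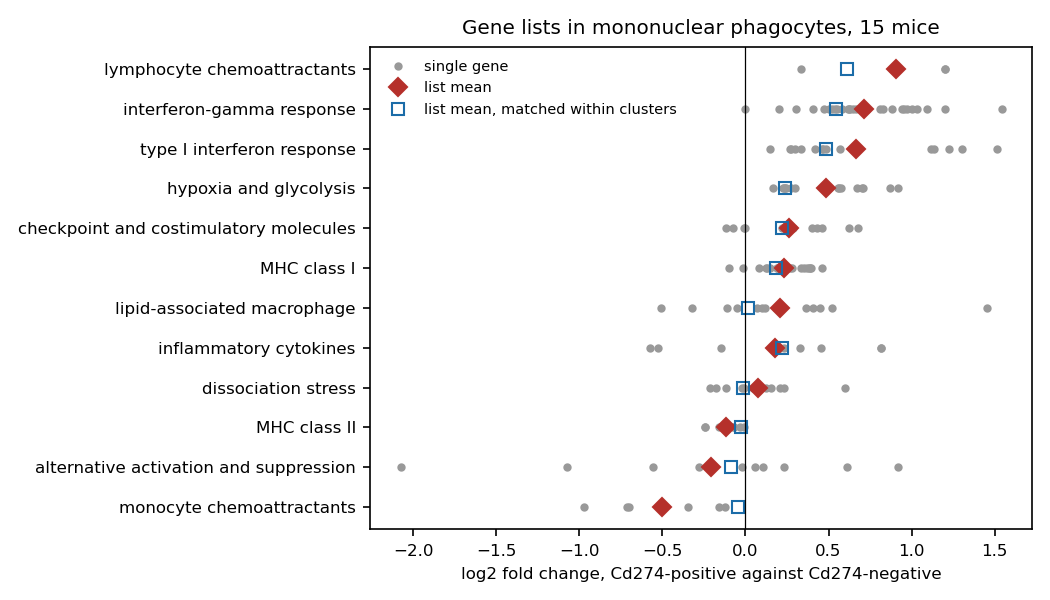
Log2 fold change between Cd274-positive and Cd274-negative mononuclear phagocytes (x axis) for each gene of a list (grey points) and the mean of each list (red diamonds), with the mean after matching cells within clusters as open squares, over 15 mice. The interferon-gamma list mean is 0.71, or 0.55 after matching, and the MHC class II list mean is -0.12.

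Matching positive and negative cells within each cluster, an alternative chosen after the data were seen, left 705 genes higher and 461 lower, with 1036 genes shared with the first fit. The interferon-gamma list then had a mean of 0.55 and 27 members higher. The hypoxia list had a mean of 0.24 and 12 members higher, while the monocyte chemoattractant mean moved to -0.04 (adjusted p = 0.366). Of 7 MHC class II genes 0 were then higher and 0 lower, with a mean of -0.02 (camera's adjusted p = 0.839), so that H2-DMb1 and H2-DMb2 no longer passed as lower. Cd200, Gpnmb and Ltc4s no longer passed.

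Cd274 transcripts were found in 67.4% ± 5.23 of mononuclear phagocytes (SD, n = 15), or in 42.8% ± 6.2 after thinning each cell to 2000 UMIs. At the same depth 7.74% of NK cell-like cells (95% exact interval 5.48 to 10.6, and 14.6% before thinning) and 1 of 29 plasmacytoid dendritic cell-like cells (3.45%, interval 0.09 to 17.8) had a Cd274 UMI. How much of this is RNA from other cells was not measured. Migratory dendritic cell-like cells had the highest share among the named classes, 69.0% of 100 cells after thinning (95% exact interval 59.0 to 77.9; 94.1% before thinning), and cDC2-like cells had 28.1% (25.6 to 30.8; 56.9% before thinning). Thinning left out 557 macrophage-like, 65 monocyte-like, 22 cDC2-like, 20 NK cell-like and 1 migratory dendritic cell-like cells. Median depths before thinning were 5309 UMIs in macrophage-like, 6031 in monocyte-like, 7245 in cDC2-like, 6792 in migratory dendritic cell-like and 3445 in NK cell-like cells. Cells with Cd274 and with a share of H2-Ab1, H2-Aa, H2-Eb1 and Cd74 transcripts above the median of the mononuclear phagocytes formed 32.7% ± 4.93, or 20.03% ± 4.27 after thinning and 22.7% ± 4.5 with at least 2 Cd274 UMIs. The log2 odds ratio between both was -0.16 ± 0.21 (SD, n = 15), below 0 in 10 of 15 mice (exact sign-flip permutation test, two-sided, p = 0.0134), but its sign turned at resolution 0.5 (0.09, exact p = 0.331; thinned -0.08, exact p = 0.42). It also did not pass at resolution 2 (-0.03, exact p = 0.593; thinned -0.09, exact p = 0.0983), with at least 2 Cd274 UMIs (-0.10, exact p = 0.0658) or with another rule for hashtags (-0.13, exact p = 0.0853). Under that rule cells were also clustered and named anew. The lowest value was -0.32, in thinned cells of at least 1000 UMIs and under 10% mitochondrial UMIs.

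Across cell classes, interferon-gamma response transcripts were highest in monocyte-like cells and MHC class II transcripts in cDC2-like cells. The interferon-gamma list summed to 9452 ± 3409 CPM in monocyte-like, 4180 ± 1180 in macrophage-like and 4898 ± 2036 in cDC2-like cells (SD, n = 15). Cluster 7 carried the monocyte-like level, with 13942 ± 3478 CPM, while the other monocyte-like cluster, cluster 0, had 4275 ± 1226 CPM and cluster 3 had 9045 ± 2624 CPM. MHC class II transcripts, which present antigen to CD4 T cells, summed to 38299 ± 2964 CPM in cDC2-like, 13904 ± 2514 in macrophage-like and 4898 ± 2058 in monocyte-like cells. Hypoxia and glycolysis transcripts were highest in macrophage-like cells, at 7527 ± 849 CPM against 4556 ± 381 in monocyte-like cells, though these genes, unlike those of the interferon and MHC lists, were open to use in clustering. Clusters 5 and 6 had the highest levels of this list, 12486 ± 1292 CPM (n = 14 mice) and 9816 ± 790 CPM (n = 15). Macrophage-like clusters 1, 3 and 4 had 5428, 4890 and 6124 CPM, beside 6129 CPM in monocyte-like cluster 0. Dissociation stress genes moved with the same classes, lower in macrophage-like than in monocyte-like cells by a log2 difference of -0.20 (higher in 2 of 15 mice, adjusted p = 0.00215) and higher in monocyte-like than in cDC2-like cells by 0.59 (15 of 15 mice, adjusted p = 8.72e-05). With cluster 3 counted as monocyte-like the first of these differences was 0.018 and no longer passed (adjusted p = 0.697, exact sign-flip test). For the interferon-gamma, MHC class II and hypoxia lists the difference between macrophage-like and monocyte-like cells had the same direction in 15 of 15 mice (exact sign-flip test, two-sided, p = 6.1e-05, the smallest it can give, adjusted p = 8.72e-05 over 30 tests). The size of the MHC class II difference, 1.59 on the log2 scale, rested on the name of cluster 3. With that cluster counted as monocyte-like the list summed to 11952 ± 2513 CPM in macrophage-like and 10280 ± 3090 in monocyte-like cells, a log2 difference of 0.24 seen in 10 of 15 mice (adjusted p = 0.0151), and at resolution 2 the difference was 0.41. At resolution 0.5, where a cluster led by S100a8 and Cxcl10 had no name, the interferon-gamma list was instead 0.39 higher in macrophage-like than in monocyte-like cells (adjusted p = 0.0044, n = 11 mice, exact sign-flip test). The monocyte-like class there was a cluster led by Pou2f2, Ifitm6 and Ace, and so of other makeup. The interferon-gamma list did not pass between macrophage-like and cDC2-like cells (-0.16, adjusted p = 0.0935), but was lower in macrophage-like cells in each of the 5 alternatives run, by log2 differences from -0.71 to -0.24.

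**Figure D3:**
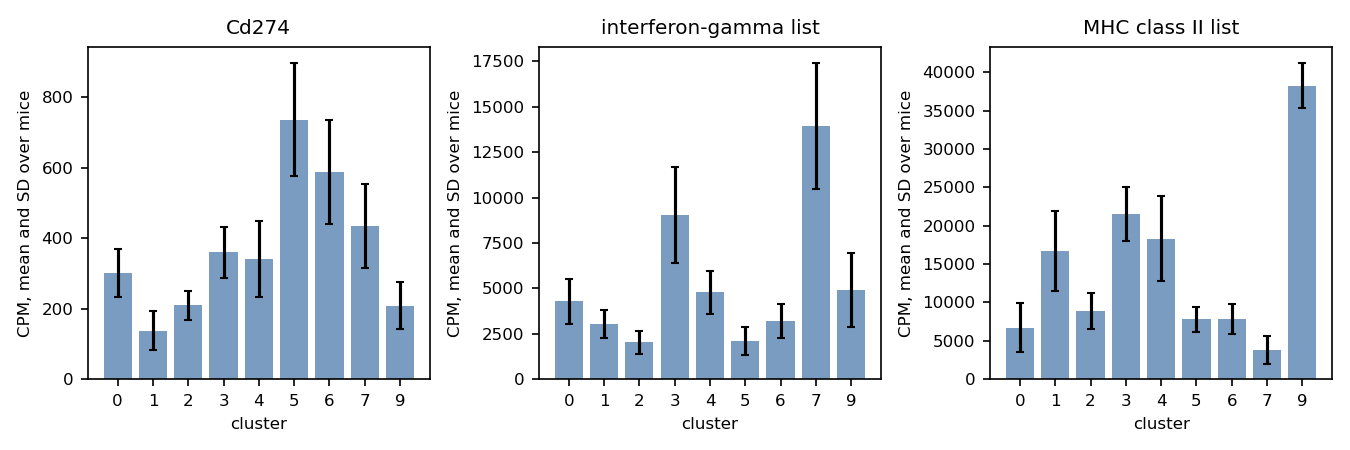
Mean CPM over mice with SD (y axis) of Cd274, the interferon-gamma list and the MHC class II list in the clusters of monocyte-like, macrophage-like and cDC2-like cells (x axis). Among these clusters, cluster 5 has the highest Cd274 level (737 CPM), cluster 7 the highest interferon-gamma list (13942 CPM) and cluster 9 the highest MHC class II list (38299 CPM).

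The study's title names macrophages induced by interferon-gamma, and the interferon-gamma list in mononuclear phagocytes was therefore compared with Ifng itself and with the NK cell-like share. Mice with more Ifng transcripts had a higher list level (Pearson r = 0.70, permutation p = 0.00333, adjusted p = 0.02; Spearman rho = 0.62, permutation p = 0.0161), and so did mice with more NK cell-like cells (r = 0.66, permutation p = 0.00734, adjusted p = 0.022; rho = 0.69, permutation p = 0.00601). Within batches neither relation passed the threshold (batch-centred r = 0.37, permutation p = 0.233, and r = 0.12, permutation p = 0.711), each batch of 5 mice being too small for its own value. Over batches 1 and 2 alone the batch-centred values were 0.60 (permutation p = 0.151) and 0.46 (permutation p = 0.329) and did not pass either. The pooled values are not adjusted for batch, and batch 3 was counted with another version of Cell Ranger. Without the 2 mice farthest from the median, both of batch 3, r was 0.79 (permutation p = 0.00143, adjusted p = 0.00858) and 0.63 (permutation p = 0.0206, adjusted p = 0.0617), so that the relation with the NK cell-like share no longer passed after adjustment. Ifng had between 0 and 32 UMIs per mouse, and 6 relations were computed in this family.

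The batches differed in many genes, most of all batch 3. Gzma, a granzyme of cytotoxic lymphocytes, was lower there, at 75.5 ± 23.1 CPM in batch 3 against 484 ± 331 in batch 1 and 451 ± 122 in batch 2 (SD, n = 5 each), beside an NK cell-like share of 0.841% against 3.71% and 3.74%. Gzmb and Nkg7 fell by 2.67 ± 0.42 and 2.34 ± 0.39 on the log2 scale against batch 1. The chemokine gene Ccl7 fell by 2.59 ± 0.27 on the log2 scale against batch 1, and Mmp12, a macrophage elastase, fell by 2.70 ± 0.44 against batch 2. Camk1d and Cmss1 were higher in batch 3, with 857 and 665 CPM against 42.4 and 4.59 in batch 1. Batches 2 and 1 differed in 2039 of 11382 genes, batches 3 and 1 in 6635 and batches 3 and 2 in 6861 by edgeR's quasi-likelihood test. In batch 2 Cxcl1 fell by 2.72 and Ccl2 fell by 1.20 on the log2 scale against batch 1. Within mononuclear phagocytes of batch 2, 10 of 14 inflammatory cytokine genes were lower than in batch 1, or 11 when adjusted over the list alone (mean -0.90; camera's adjusted p = 1.37e-08). Type I interferon response genes were lower in 13 of 18 cases, or 16 when adjusted over the list alone (mean -0.66; camera's adjusted p = 1.53e-10), and dissociation stress genes were lower in 5 of 13, or 8 when adjusted over the list alone (mean -0.39; camera's adjusted p = 0.000442). With an estimated correlation each of these 3 lists had adjusted p = 0.376. Interferon-gamma response genes in mononuclear phagocytes were lower in batch 3 than in batch 1 in 25 of 29 cases (26 when adjusted over the list alone, mean -1.05; camera's adjusted p = 9.92e-07, and adjusted p = 0.531 with an estimated correlation), as were 8 of 13 dissociation stress genes (9 when adjusted over the list alone, mean -0.39; camera's adjusted p = 0.0332, and adjusted p = 0.531 with an estimated correlation). Batch 3 was counted with another version of Cell Ranger, and genes with long introns were higher in it. The group of genes with the shortest introns was lower, with a median log2 fold change of -0.338 against the mean of batches 1 and 2. How far this shift enters the falls in batch 3 given above was not tested.

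**Figure D4:**
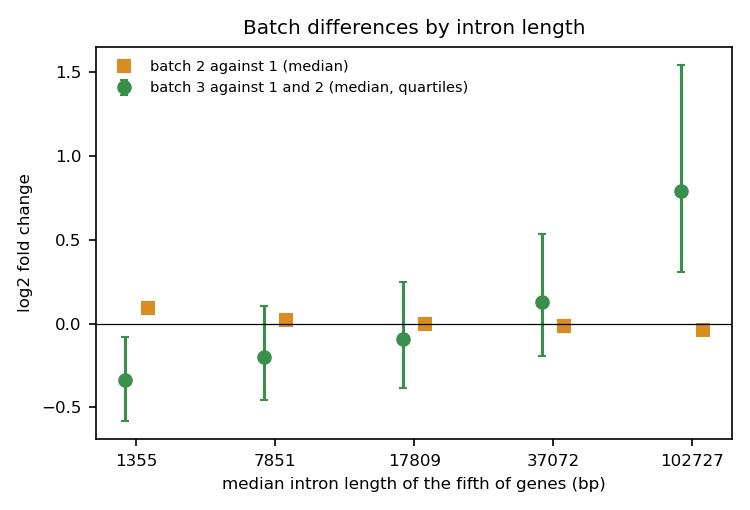
Log2 fold change (y axis) of genes sorted into 5 groups by total intron length, labelled with the median length in bp (x axis), for batch 3 against the mean of batches 1 and 2 (circles, median with quartiles) and for batch 2 against batch 1 (squares, median). The median rises from -0.34 in the group with the shortest introns to 0.79 in the group with the longest.

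Cd274 lies on chromosome 19 from 29367455 to 29388095 (ENSMUSG00000016496, plus strand), Cxcl9 on chromosome 5 from 92321347 to 92328079, Slamf7 on chromosome 1 from 171632403 to 171653035, Inhba on chromosome 13 from 16011851 to 16031621 and Cd163 on chromosome 6 from 124304656 to 124330527 (mm10, GENCODE M21), all protein-coding. Ifit3, Tgtp2, H2-Q6, H2-Q7 and genes of the Gbp family have near-identical copies, and their counts are uncertain.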

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

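The swaps of Cd274-positive and Cd274-negative sums and the tests of cluster makeup and depth for the Cd274 lists were chosen after their results were seen, and the batch interaction and the comparison of batches within mononuclear phagocytes alone were added after the data were seen.

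Among 246 groups of 5 mice examined for a mouse apart from the others, 15 values stood apart, and chance gives about 1 in 20 groups. Igkc, an immunoglobulin light chain gene, stood at 2004 CPM in batch 3 mouse 4 against at most 3.29 CPM in the other 4 mice of that batch, and at 10.9 CPM in batch 2 mouse 5. Gzmf reached 101 CPM in batch 1 mouse 5, and Retnla 120 CPM in batch 1 mouse 4 and 119 CPM in batch 2 mouse 2. Migratory dendritic cell-like cells formed 1.61% in batch 3 mouse 4, and cluster 12 formed 2.01% in batch 2 mouse 5. In the same mouse the inflammatory cytokine list stood at 5382 CPM and Nr4a1 at 99.2 CPM. The hypoxia list stood at 7434 CPM in batch 1 mouse 1, the monocyte chemoattractant list at 7736 CPM in batch 1 mouse 4 and the cytotoxic list at 13.8 CPM in batch 2 mouse 4. Single genes apart were Arl15 with 9.44 CPM in batch 2 mouse 3, Ccl2 with 1060 CPM in batch 3 mouse 5 and Slc7a5 with 5.77 CPM in batch 1 mouse 3.

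The Cd274 comparison differed between batches in 2 of 7978 genes, Ifi205 (adjusted p = 0.00802) and Ifit3 (adjusted p = 0.0407), by a test of the interaction in edgeR, with 561 genes at an unadjusted p under 0.05. The log2 difference of Ifit3 was 1.05, 0.42 and 2.58 in batches 1, 2 and 3, and that of Ifi205 was 0.75, 0.78 and 1.85.

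Genes of the interferon-gamma list and of hypoxia were both higher in Cd274-positive cells. Makeup by the clusters of resolution 1 is argued against as the whole cause, since cells matched within clusters gave list means of 0.55 and 0.24. Genes of the interferon-gamma list were left out of the clustering, so cells of unlike interferon state can share a cluster, and matching does not cover such makeup. Hypoxia genes were open to clustering, and 12 of 15 were still higher after matching. Depth is argued against too, since all negative cells, unmatched in depth, gave 0.76 and 0.41 beside 0.71 and 0.48. Of 100 swaps of the sums within mice, 1, the real one, gave as many as 2682 genes, and the highest other gave 739. This argues against chance as far as 100 swaps can show. The other swaps mix positive and negative sums on each side, so that the Cd274 difference enters their spread, and their median was 0 genes. RNA from other cells and doublets within a mouse stay open, and no biological explanation was tested.

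Genes higher in batch 3 may reflect intronic reads counted in that batch only, a candidate explanation prompted by the software versions and the leading genes of cluster 11, with a test set before its result was seen. The median log2 fold change in the group of genes with the longest introns, of 5 groups, exceeded that in the group with the shortest by 1.13 (95% bootstrap interval 1.09 to 1.19 over genes), against -0.13 between batches 2 and 1. A shift between mononuclear phagocytes and other classes is argued against as the whole cause. Within mononuclear phagocytes alone 3056 of 10599 genes were higher in batch 3 than in batch 1, beside 3401 of 11382 in all cells. In both directions together 55.7% and 58.3% passed. Shifts among the clusters of mononuclear phagocytes are not covered, such as that of cluster 7 (6.92% of cells in batch 3, 11.9% in batch 1). In each of the 3 batch comparisons 1 of 100 splits of the 10 mice, the real one, gave as many genes, with highest others of 27, 1 and 1 against 1971, 6205 and 6755 in a fit of those 10 mice alone. This argues against chance as far as 100 splits can show. The other splits mix mice of both batches, so that the batch difference enters their spread. Treatment, tissue and library chemistry of the batches are not known and stay open.

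Cluster 12, led by Retnlg, Alox15 and Ccr3, held 12.5% ± 3.49 of the cells in batch 3 (SD, n = 5) and 0.634% ± 0.54 in batches 1 and 2 (n = 10). Its highest marker score was that for eosinophils (3.486), though the naming rule left it unnamed. Deeper libraries in batch 3 are argued against as the whole cause: with each cell of batch 3 thinned by one factor of 0.646, set from the median UMIs of mononuclear phagocytes in batches 3 and 1 (8236 and 5323), its mean fell from 12.5% to 9.51% and its lowest mouse held 7.04%, above the 2.01% of the highest mouse of the other batches. The depth of the cells of cluster 12 themselves was not matched. Cell calling by another software version was not tested and stays open, and no biological explanation was tested.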

How the results depend on the processing

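Alternatives added after the data were seen were, in the Cd274 comparison, cells of 1000 UMIs, the margin rule for hashtags, removal of the top Scrublet scores, matching within clusters, the added Ace cluster, and RLE factors, and elsewhere mononuclear phagocytes alone and leaving out mice in the batch comparison, batch 3 against the mean of the others, all settings of the odds ratio, other names and resolutions for the levels by class, and 4 of the 6 relations. The planned comparisons of conditions, and sequencing lanes as separate libraries, were not run, because no mouse has a condition and barcodes do not separate lanes.

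The count of 2682 genes in the Cd274 comparison ran from 2482 to 2709 without any one mouse. It fell to 774 without the replicate block of mouse (461 higher, 313 lower), because differences between mice then enter the spread, to 1166 (705 and 461) matched within clusters, to 1739 with DESeq2 (1132 higher, 607 lower) and to 1623 without batch 2 (668 lower), and without batch 1 840 genes were lower. Library numbers in the labels pair no mice. The interferon-gamma, type I interferon, hypoxia, MHC class I, checkpoint, inflammatory and lymphocyte chemoattractant lists kept direction and threshold in each alternative in which lists were tested, with interferon-gamma means from 0.55 to 0.89 and hypoxia means from 0.24 to 0.63. Among single genes Cd200, Gpnmb and Ltc4s no longer passed within clusters, where their log2 fold changes shrank to 0.41, 0.38 and -0.16. Without the block Cd200, Ltc4s, Psd3, Pf4, Cd209a and Slc9a9 did not pass either. Their log2 fold changes there, 1.52, -1.25, -1.45, -1.23, -1.20 and -1.07, stayed close to those of the first fit.

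The lipid-associated list lost its call with all negative cells (0.16), at least 2 Cd274 UMIs (0.19), the margin rule (0.079), without top Scrublet scores (0.14), matched within clusters (0.014), without the block (0.20) and with an estimated correlation (0.21), and ran from 0.17 to 0.23 without single mice, with the call lost without batch 1 mouse 4 (0.175) or batch 3 mouse 3 (0.17). Monocyte chemoattractants lost theirs within clusters (-0.043). MHC class II passed as lower with cells of 1000 UMIs (-0.18) and the margin rule (-0.15), and dissociation stress as higher with the margin rule (0.13) and without a count filter (0.086). The cause was not tested.

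In the levels by class, 5 alternatives were run: cells of 1000 UMIs, cluster 3 as monocyte-like, clusters 3 and 6 as monocyte-like, and resolutions 2 and 0.5. In that order, the interferon-gamma difference of macrophage-like and cDC2-like cells, -0.16 and not passed before, passed at -0.49, -0.69, -0.71, -0.55 and -0.24, the MHC class I difference of macrophage-like and monocyte-like cells, 0.011 and not passed before (adjusted p = 0.575), passed at -0.18, -0.33, -0.24, -0.12 and 0.31, and that of monocyte-like and cDC2-like cells, 0.035 before (adjusted p = 0.298), at 0.16, 0.21, 0.15, 0.12 and -0.26. With cluster 3, and with clusters 3 and 6, as monocyte-like, MHC class I of macrophage-like and cDC2-like cells, 0.046 before (adjusted p = 0.122), passed at -0.11 and -0.090, and the cell cycle difference of monocyte-like and cDC2-like cells, 0.084 before (adjusted p = 0.284), passed at 0.25 and 0.23, as at resolution 2 (0.21). Dissociation stress of macrophage-like and monocyte-like cells turned from -0.20 to 0.018 with cluster 3 moved, and checkpoint genes of the same classes from -0.13 to 0.040 at resolution 2, neither passing. With cells of 1000 UMIs the inflammatory difference of macrophage-like and monocyte-like cells no longer passed (-0.18) and type I interferon of macrophage-like and cDC2-like cells, 0.010 before (adjusted p = 0.922), passed at -0.45. With this filter a shallow cluster of 318 cells led by Gm42418 was counted as monocyte-like, while the cluster led by that gene had no name before. At resolution 0.5 differences of macrophage-like and monocyte-like cells reversed for interferon-gamma (0.39), type I interferon (0.25), checkpoint (0.77) and inflammatory genes (0.43), those of monocyte-like and cDC2-like cells for interferon-gamma (-0.73), type I interferon (-0.43), checkpoint (-0.42) and hypoxia genes (-1.17), with inflammatory genes no longer passing (0.27), and cell cycle of macrophage-like and cDC2-like cells turned to -0.058. The type I interferon and cell cycle values did not pass there. In that setting the monocyte-like class held 3.64% of cells in place of 20.8%. The cause of these changes was not tested further.

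Within batches the relations with Ifng (0.37) and NK cell-like share (0.12) no longer passed, and the latter (0.63) did not pass without the 2 farthest mice. The odds ratio of Cd274 and MHC class II was 0.088 at resolution 0.5, reversed, and missed the threshold at 2 Cd274 UMIs (-0.10), the margin rule (-0.13), resolution 2 (-0.033, thinned -0.090) and resolution 0.5 thinned (-0.077). It was larger with cells of 1000 UMIs (-0.24, thinned -0.32) and with the margin rule thinned (-0.29). The cause was not tested. Batch counts stayed within 1.5 times, from 1503 to 2143, 6365 to 6725 and 6510 to 7054 without single mice. Depth limits Ifng, with at most 32 UMIs per mouse.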

Other observations

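The levels of single clusters and the 12 tests between them were chosen after the data were seen. Among the clusters of monocyte-like, macrophage-like and cDC2-like cells Cd274 was highest in cluster 5, macrophage-like cells led by Mmp12, Inhba, Gpnmb and the hypoxia-induced gene Hilpda, with 737 ± 161 CPM (SD, n = 14 mice), and in cluster 6, led by Hspa1b, Hmox1 and Slc2a1, with 588 ± 148 CPM. Cluster 7, monocyte-like cells led by Cxcl10, Cxcl9 and Gbp5, had 434 ± 121 CPM of Cd274. Over these 3 clusters the interferon-gamma list had the opposite order, with 2092 ± 774 CPM in cluster 5, 3218 ± 931 CPM in cluster 6 and 13942 ± 3478 CPM in cluster 7. Over clusters 7, 3, 4 and 0, picked after their levels were seen, both fell together, with 434, 360, 341 and 301 CPM of Cd274 and 13942, 9045, 4774 and 4275 CPM of the list, and cluster 2 had 209 and 2015 CPM. Cluster 1 broke this order, with less Cd274 than cluster 2 and more of the list. Cd274 was 0.76 ± 0.35 higher on the log2 scale in cluster 5 than in cluster 7, in 14 of 14 mice (exact sign-flip test, two-sided, p = 0.000122, the smallest it can give; adjusted p = 0.000183), while the interferon-gamma list differed by -2.80 ± 0.36 in the other direction in 14 of 14 mice. Cxcl9, a chemokine that attracts T cells, stood at 158 ± 121 CPM in cluster 5 and 2491 ± 968 CPM in cluster 7. Against cluster 1 the log2 difference of cluster 5 was 2.55 for Cd274 (13 of 13 mice), -0.52 for the interferon-gamma list (higher in 1 of 13 mice, adjusted p = 0.000533, exact test) and 1.07 for Cxcl9, which did not pass (10 of 13 mice, adjusted p = 0.0776, exact test). Cd274, Cxcl9 and the genes of the interferon-gamma and MHC class II lists were kept out of the genes used for clustering. Other genes that lead these clusters, such as Calhm6 in cluster 7 and Hilpda in cluster 5, were open to use there. The clusters were compared after their levels were seen. These p-values thus show how alike the mice were and do not test the choice of clusters.

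MHC class II transcripts separated the clusters in another way. They summed to 21565 ± 3490 CPM in cluster 3, whose macrophage and monocyte scores were nearly tied, with 2674 ± 1047 CPM of Cxcl9, and to 3827 ± 1840 CPM in cluster 7. Across the 15 mice the Cd274 level in mononuclear phagocytes did not pass after adjustment in its relation with the interferon-gamma list (r = 0.55, permutation p = 0.0339, adjusted p = 0.0677; rho = 0.40, permutation p = 0.137; batch-centred r = 0.71, permutation p = 0.0147, adjusted p = 0.088), and r was 0.29 without the 2 mice farthest from the median, so that the pooled relation rests on those mice. Over batches 1 and 2 alone, which hold neither mouse, the batch-centred r was 0.68 (permutation p = 0.0829). Cd274 had no detected relation with the MHC class II list (r = 0.09, permutation p = 0.749; rho = -0.08, permutation p = 0.772; batch-centred r = 0.06; r = -0.04 without 2 mice) or the hypoxia list (r = 0.45, permutation p = 0.0963; rho = 0.39, permutation p = 0.156; batch-centred r = 0.39; r = 0.41 without 2 mice). The interferon-gamma and MHC class II lists had r = 0.17 (permutation p = 0.538; rho = 0.26, permutation p = 0.342; batch-centred r = -0.36), and r = 0.57 without 2 mice. These 4 relations, chosen after the data were seen, belong to the family of 6.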
